A study of Homo sapiens with 6 samples.

How the data were processed

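RNA was measured in 6 libraries of T24 bladder cancer cells, 3 labelled negative control and 3 labelled FOXF1-activated, and the groups were taken from the treatment labels. The deposited table gives whole-number counts per gene for 60612 Ensembl identifiers in each of the 6 libraries, and the authors applied no normalisation that the values show. Per the submitters' processing notes, the tools included cutadapt 1.9 and TopHat2 2.0.4 and the genome build was GRCh38. The counting tool, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping and antisense genes may be shared. Counts of 4, 8 and 12 occurred 2.36, 1.94 and 1.60 times as often as the neighbouring values, so part of the counts may be multiples of the fragments seen, and the depth may be overstated. Library totals were 72500854 to 77198669 counts.

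Symbols were taken from a table of Ensembl identifiers and matched 60401 identifiers, 20258 of the 20334 tested. Coordinates are those of GENCODE 29 on GRCh38, which held 58394 of the identifiers. The deposited table holds identifiers that this release lacks, so the annotation used for counting was not the same.

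Genes were kept by filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), which left 20334 genes. Libraries were scaled by TMM, and the groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no covariates. The standard error of a log2 fold change was its size divided by the square root of F. Levels are TMM-scaled CPM, with SD over 3 libraries. Gene lists were tested with camera in limma 3.58.1 on voom values, with an inter-gene correlation of 0.01, for lists with at least 5 tested genes. The same test with an estimated correlation and fry were run beside it. Fry's directional p tests whether a list's genes move, on balance, in a direction, and does not compare the list with other genes.

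The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The rule named FOXF1 and its tested neighbours on chromosome 16, and the 12 genes with the largest positive and the 12 with the largest negative fitted changes. Those 24 had to pass the threshold, reach a mean of 5 CPM in the higher group, show no overlap between the libraries of the groups and carry a symbol that is not a clone or locus identifier. It also named up to 4 members with the smallest p in each described list, and several apoptosis and proliferation genes (among them CASP8, CASP9, BAX, BCL2, MCL1, BIRC5, CDKN1A, MKI67 and CDH1) wherever tested. Some genes that the rule names are not reported here. Y-linked genes and XIST were left out.

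Alternatives were other scalings (DESeq2's size factors, upper quartile, library totals), no filter, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number in the model, a prior count of 2 and leaving out each library. Chosen after seeing the data were counts divided by 4, offsets for GC content and transcript length, and leaving out the 50 genes with the highest counts. Counts of replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of 19.5 to 33.4 (5.29 to 9.19 with counts divided by 4), so no library was treated as a duplicate.

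The gene test was checked on simulated data for this comparison, with 20334 genes drawn from the real means and dispersions. It recovered 40 of 67 genes changed by 1.5-fold, 44 of 67 changed by 2-fold and 65 of 66 changed by 4-fold. Of its 169 calls 20 were false, a larger share than the adjusted p threshold is meant to allow. Only these genes were changed in the simulation, whereas 60.7% of tested genes were called in the real comparison. The check therefore does not show the share of false calls when so many genes change. The list test called the raised list and 0 of 19 unchanged lists. Whether the simulated genes were correlated is not given, so this result cannot show how the list test behaves with correlated genes.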

Results

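RNA sequencing was carried out on T24, an established human bladder cancer cell line, after lentiviral delivery of a short hairpin and puromycin selection. In 3 libraries, labelled FOXF1-activated, the hairpin was derived from a small activating RNA aimed at the promoter of FOXF1, a forkhead transcription factor. Small activating RNAs are short duplexes designed to raise transcription of the gene whose promoter they match. The other 3 libraries, labelled negative control, carried a control hairpin. Total RNA was depleted of ribosomal RNA and made into stranded libraries. Gene counts summed to 72500854 to 77198669 per library, over 60612 gene identifiers, of which 25268 to 26862 had a count above 0 in a library. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

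The first question was the level of FOXF1 itself, the gene that the activating hairpin was designed to raise. FOXF1 (ENSG00000103241; GRCh38, GENCODE 29, chromosome 16, 86510527 to 86515418, plus strand) was lower in the libraries labelled FOXF1-activated. Its normalised level was 7.51, 7.10 and 7.95 CPM (counts scaled to library size) in the negative control libraries 1, 2 and 3. It was 5.94, 4.78 and 5.10 CPM in the libraries labelled FOXF1-activated. The means were 7.52 ± 0.43 and 5.27 ± 0.60 CPM (SD, n = 3 each), a log2 fold change of -0.51 with a standard error of 0.14 and an edgeR adjusted p of 0.0109. All 3 libraries labelled FOXF1-activated lay below all 3 controls. The raw counts behind these levels were 545 to 599 in the controls and 339 to 418 in the other group. Because the targeted gene ran against the label, each direction below refers to the libraries labelled FOXF1-activated relative to those labelled negative control.

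Genes near FOXF1 on chromosome 16 moved in different directions. Of the 9 tested, FOXF1 included, 3 were higher and 3 lower. Since 60.7% of all tested genes were called, such moves need not be particular to this region. FENDRR, a long noncoding RNA gene on the opposite strand (86474529 to 86509099), was at 3.55 ± 0.38 and 3.23 ± 1.20 CPM (SD, n = 3), with a log2 fold change of -0.14 that did not pass the test (edgeR adjusted p = 0.669). FOXC2 (86566829 to 86569728) was at 3.41 ± 0.10 and 3.24 ± 0.39 CPM, also without a call (log2 fold change -0.07, edgeR adjusted p = 0.736). The sign of the FOXC2 value turned under upper-quartile scaling (0.025), under offsets for GC content and length (0.21) and without FOXF1-activated replicate 3 (0.015), and that of FENDRR turned without FOXF1-activated replicate 2 (0.046). FOXL1 (86576368 to 86582160) rose from 20.02 ± 0.49 to 34.4 ± 3.0 CPM, a log2 fold change of 0.78 (edgeR adjusted p = 3.40e-05). MTHFSD, between FOXF1 and FOXC2, fell from 18.3 ± 0.9 to 12.2 ± 0.2 CPM, a log2 fold change of -0.59. Farther away, FBXO31 and COX4I1 rose (log2 fold changes 0.51 and 0.42), GINS2 fell (-1.51), and EMC8 did not pass the test (0.13, edgeR adjusted p = 0.299).

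**Figure D1:**
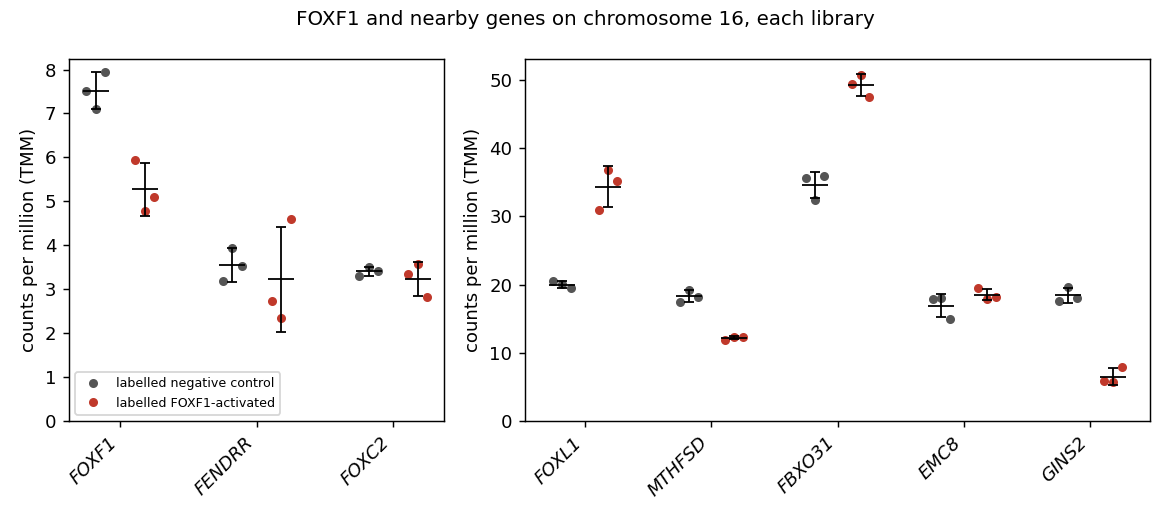
Normalised level (CPM, y axis) of FOXF1 and 7 nearby genes on chromosome 16 (x axis) in each library, grey for negative control and red for FOXF1-activated as labelled; points are libraries and bars show mean and SD (n = 3). FOXF1 was at 7.10 to 7.95 in the controls and 4.78 to 5.94 in the libraries labelled FOXF1-activated.

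The comparison of the groups over all genes asked which transcripts differed with the hairpin. Of 20334 genes tested, 12351 (60.7%) changed at an edgeR adjusted p under 0.05. In the libraries labelled FOXF1-activated, 5944 genes were higher and 6407 were lower, and 5863 of the changed genes differed by at least 2-fold. The libraries of the groups did not overlap for 68.8% of tested genes, where chance gives 10% for 3 against 3. The first principal component of log2 CPM carried 70.8% of the variance and put the 3 libraries of each label on opposite sides.

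Composition of the libraries moved with the label. FN1, which encodes the matrix protein fibronectin (chromosome 2, 215360440 to 215436172), took 3.34 ± 0.10% of counts in the controls and 0.282 ± 0.005% in the libraries labelled FOXF1-activated (SD, n = 3 each). Mitochondrial transcripts took 5.28 ± 0.21% and 6.76 ± 0.44%. The mitochondrial ribosomal RNAs, which are residual structural RNAs in a depleted library, took 0.394 ± 0.011% and 0.813 ± 0.018%. For these 3 shares the libraries of the labels did not overlap.

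The largest rises, by the rule set for named genes, included the chemokine genes CXCL8 and CXCL2. CXCL8, a neutrophil-attracting chemokine (chromosome 4, 73740506 to 73743716), rose from 26.4 ± 16.7 to 856 ± 85 CPM, a log2 fold change of 5.02 with a standard error of 0.39 (edgeR adjusted p = 2.93e-06). Its control libraries were at 45.7, 16.2 and 17.3 CPM, and without negative control replicate 1 their mean was 16.7 CPM and the log2 fold change 5.67. CXCL2, a chemokine of the same family (chromosome 4, 74097035 to 74099293), rose from 6.42 ± 2.91 to 216 ± 31 CPM, with a log2 fold change of 5.07 and a standard error of 0.28. DUSP8, which encodes a MAP kinase phosphatase, rose from 0.508 ± 0.275 to 19.8 ± 0.6 CPM (log2 fold change 5.28). The noncoding RNA RDUR rose by 5.37 on the log2 scale to 29.9 ± 3.6 CPM, and CLDN6, a tight-junction claudin, by 5.42 to 10.3 ± 3.0 CPM. BEST2 (7.09), FBXW10 (6.34), FNDC7 (5.94), IFITM10 (5.18) and PROZ (5.09) completed the group of uniquely named genes. HSD3BP5, a pseudogene (5.35), and SPANXB1, of a multigene family (5.02), can share reads with near-identical copies and are uncertain. BEST2 held 11 counts over the 3 control libraries together, FBXW10 20 and FNDC7 29, so the sizes of these fitted changes depend on the prior count. Leaving out negative control replicate 1 gave log2 fold changes of 7.98 for FBXW10, 12.15 for FNDC7 (with 0 control counts left), 6.38 for IFITM10 (75 control counts in all), 6.46 for HSD3BP5 and 6.18 for SPANXB1.

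The largest falls, by the same rule, included FGFBP1. This gene, which encodes a secreted carrier of fibroblast growth factors (chromosome 4, 15935569 to 15938740), fell from 261 ± 43 to 7.03 ± 1.18 CPM, a log2 fold change of -5.21 with a standard error of 0.16 (edgeR adjusted p = 1.76e-08). PPL, the desmosome-associated protein periplakin, fell from 79.0 ± 9.0 to 2.37 ± 0.39 CPM (log2 fold change -5.06). The potassium channel gene KCNK3 fell from 47.8 ± 1.3 to 1.12 ± 0.36 CPM (-5.42), and SCNN1A, a subunit of the epithelial sodium channel, from 41.4 ± 3.6 to 1.49 ± 0.31 CPM (-4.79). PYCARD, the inflammasome adaptor ASC, fell from 8.89 ± 1.66 to 0.258 ± 0.275 CPM (-5.08). The remaining genes were NIPAL4 (-5.01), the potassium channel gene KCND2 (-4.67), the Toll-like receptor adaptor gene TICAM2 (-4.66), PADI3 (-4.55), GPRC5C (-4.31), OASL (-4.28) and CYS1 (-4.14). PYCARD held 57 counts over the libraries labelled FOXF1-activated and TICAM2 59, most of them in replicate 3. Without that library PYCARD was at 0.114 CPM (log2 fold change -6.28) and TICAM2 at 0.121 CPM (-5.82).

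**Figure D2:**
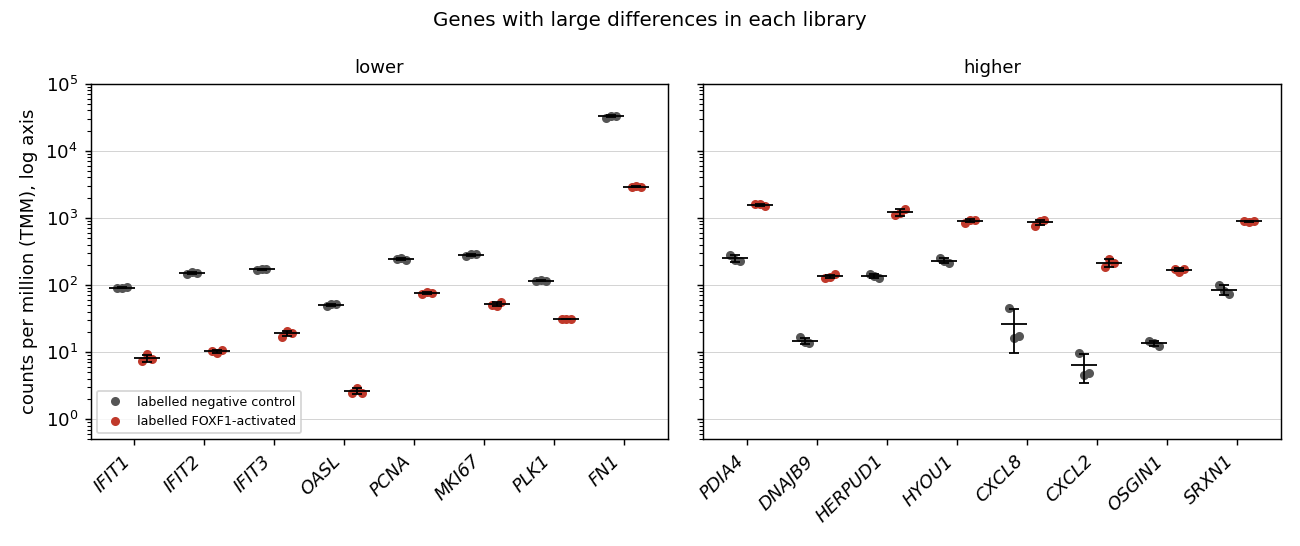
Normalised level (CPM, log y axis) of 16 genes (x axis) in each library, grey for negative control and red for FOXF1-activated as labelled; points are libraries and bars show mean and SD (n = 3). CXCL8 went from 26.4 (16.7 without negative control replicate 1) to 856 and IFIT2 from 151 to 10.3 CPM.

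Gene lists fixed in advance were tested as sets with camera. Of 35 lists tested, 15 were called at an adjusted p under 0.05 with a preset inter-gene correlation of 0.01, 10 higher and 5 lower. With the correlation estimated from the data camera called 0 lists, with 7 at an unadjusted p under 0.05, while fry called 30 for movement in a net direction. Apoptosis inhibitors and the autophagy and lysosome list lost their calls although their estimated correlations (-0.086 and 0.0072) lay below the preset 0.01. A higher correlation does not account for every loss. With an estimated correlation camera also limits its degrees of freedom to the residual ones, which are few with 6 libraries. The p with an estimated correlation stands beside each called list and does not measure gene correlation alone.

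Interferon-stimulated genes, antiviral effectors and sensors that interferons induce, fell as a group. All 35 tested members were lower, 35 also when adjusted over the list alone, with a median log2 fold change of -2.35 (camera adjusted p = 2.06e-14, and adjusted p = 0.126 with an estimated correlation). IFIT2 fell from 151 ± 7 to 10.3 ± 0.5 CPM (log2 fold change -3.87, standard error 0.07, edgeR adjusted p = 4.50e-09). IFIT3 (-3.17), IFIT1 (-3.49) and OASL (-4.28), a member of the oligoadenylate synthetase family, fell likewise. Under upper-quartile scaling 34 of the 35 genes were called, as also without negative control replicate 1 and without FOXF1-activated replicate 1 or 3.

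Genes of double-stranded RNA sensing and small RNA processing went both ways, 5 of 14 higher and 5 lower, 5 and 5 adjusted over the list alone (camera adjusted p = 0.861). AGO2, the Argonaute slicer, rose from 146 ± 10 to 418 ± 6 CPM (log2 fold change 1.51). DICER1 (1.24) and XPO5 (1.13), which process and export precursor small RNAs, rose as well, and the RNA receptor TLR3 fell (-2.63).

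Proliferation genes were lower. All 24 genes of the G2/M and mitosis list fell, 24 adjusted over the list alone, with a median log2 fold change of -1.61 (camera adjusted p = 4.76e-13, and adjusted p = 0.182 with an estimated correlation). MKI67, which encodes the proliferation marker Ki-67, fell from 281 ± 9 to 51.5 ± 3.6 CPM, a log2 fold change of -2.45 with a standard error of 0.07. The mitotic kinase gene PLK1 (-1.89), the transcription factor gene FOXM1 (-1.94) and the topoisomerase gene TOP2A (-2.23) fell too. In the G1/S and DNA replication list, 23 of 26 genes were lower and 1 was higher, 23 and 2 adjusted over the list alone (median -0.98, camera adjusted p = 2.25e-07, and adjusted p = 0.205 with an estimated correlation), with 2 higher without FOXF1-activated replicate 1, under DESeq2's size factors or test, upper-quartile scaling, GC and length offsets or the 1 CPM filter, and with counts divided by 4. Examples were the replication clamp gene PCNA (-1.69), UHRF1 (-1.77), E2F1 (-1.99) and RRM2 (-1.59). Replication-dependent histones were not called (6 of 14 higher and 1 lower, 6 and 1 adjusted over the list alone, camera adjusted p = 0.254; 0 lower of 7 with the 1 CPM filter), with H1-2 at 1.18 and H2AC6 at 0.57. Of the p53 targets, 6 of 20 rose and 9 fell, 6 and 9 adjusted over the list alone (camera adjusted p = 0.816). CDKN1A, the cell cycle inhibitor p21, fell (-0.85), as did FDXR (-1.87) and TP53I3 (-2.53), while AEN (1.25) and SESN2 (1.45) rose.

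Genes of endoplasmic reticulum and amino acid stress rose. In this list 16 of 21 genes were higher and 4 were lower, 16 and 4 adjusted over the list alone, with a median log2 fold change of 1.75 (camera adjusted p = 1.75e-05, and adjusted p = 0.205 with an estimated correlation), and 2 were lower under GC and length offsets. The co-chaperone gene DNAJB9 rose from 14.8 ± 1.6 to 134 ± 9 CPM, a log2 fold change of 3.18 with a standard error of 0.09 (edgeR adjusted p = 1.49e-08). HERPUD1, of endoplasmic reticulum degradation, rose by 3.14 on the log2 scale, the disulfide isomerase gene PDIA4 by 2.65, and the chaperone gene HYOU1 by 1.97.

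Targets of NRF2, the transcription factor of the antioxidant response, were higher for 16 of 20 genes and lower for 1, 17 and 1 adjusted over the list alone (median 1.30, camera adjusted p = 2.25e-07, and adjusted p = 0.252 with an estimated correlation). SRXN1, sulfiredoxin, rose from 85.0 ± 13.3 to 895 ± 17 CPM (log2 fold change 3.40). OSGIN1 (3.64), AKR1C1 (2.73) and the cystine transporter gene SLC7A11 (2.47) rose with it. Genes of autophagy and lysosome were higher for 15 of 20 and lower for 3, 15 and 3 adjusted over the list alone (median 0.74, camera adjusted p = 4.61e-04, and adjusted p = 0.182 with an estimated correlation), among them SQSTM1 (1.40), the autophagy receptor p62, and GABARAPL1 (1.64). Cholesterol synthesis and uptake genes fell for 19 of 23 and rose for 2, 19 and 3 adjusted over the list alone (median -0.50, camera adjusted p = 2.09e-05, and adjusted p = 0.205 with an estimated correlation), with EBP at -1.29 and SQLE at -0.65, and 1 rose with library totals only, with no filter, and without negative control replicate 1 or 3 or FOXF1-activated replicate 3. Hypoxia and glycolysis genes split, with 9 of 22 higher and 7 lower, 9 and 7 adjusted over the list alone (camera adjusted p = 0.474). VEGFA, the angiogenic growth factor, fell (-2.06), while the hexokinase gene HK2 (2.17) and the glucose transporter gene SLC2A3 (1.62) rose.

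Of the 21 genes tested in the list of NF-kB and inflammatory cytokines, 18 were higher and 1 was lower, 18 and 1 adjusted over the list alone (median 1.22, camera adjusted p = 5.39e-07, and adjusted p = 0.205 with an estimated correlation). Besides CXCL8 and CXCL2, IL1A rose from 75.5 ± 3.7 to 333 ± 14 CPM (log2 fold change 2.14), CXCL3 by 4.13, CXCL1 by 2.39 and the adhesion receptor gene ICAM1 by 1.21. MAPK feedback and immediate early genes were higher for 14 of 18 and lower for 3, 14 and 3 adjusted over the list alone (median 1.01, camera adjusted p = 1.08e-04, and adjusted p = 0.182 with an estimated correlation), with 1 lower under GC and length offsets. They included IER3 (1.95), SPRY4 (1.19) and DUSP4 (1.96). YAP/TAZ targets were higher for 10 of 16 and lower for 2, 11 and 2 adjusted over the list alone (median 0.74, camera adjusted p = 0.00317, and adjusted p = 0.205 with an estimated correlation). In that list CCN2 rose from 23.6 ± 7.7 to 404 ± 10 CPM (log2 fold change 4.10), AMOTL2 by 1.39 and the kinase gene LATS2 by 2.02.

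Apoptosis genes moved in several directions. Of 11 apoptosis inhibitors, 8 were higher and 1 was lower, 8 and 1 adjusted over the list alone (median 0.61, camera adjusted p = 0.0127, and adjusted p = 0.205 with an estimated correlation). BIRC3 (1.78), BIRC2 (0.81), XIAP (0.77) and MCL1 (0.49) rose, BIRC5, which encodes survivin, fell (-1.53), and BCL2 had a log2 fold change of -0.12 without a call (edgeR adjusted p = 0.336). Caspases and apoptosome genes were 6 higher and 6 lower of 15, 6 and 6 adjusted over the list alone (camera adjusted p = 0.861), with opposite net directions in camera and fry. The initiator caspase gene CASP8 fell from 52.3 ± 2.2 to 37.5 ± 0.8 CPM (log2 fold change -0.48). CASP9 was higher by 0.41 (edgeR adjusted p = 0.0184), a call lost without negative control replicate 3 (0.34, adjusted p = 0.0704) and without FOXF1-activated replicate 3 (0.37, adjusted p = 0.0639). Pro-apoptotic BCL2 family genes were 4 higher and 4 lower of 11, 5 and 5 adjusted over the list alone (camera adjusted p = 0.816), with 2 lower under upper-quartile scaling and without negative control replicate 2 or FOXF1-activated replicate 1. BMF fell from 47.5 ± 0.3 to 4.83 ± 0.39 CPM (log2 fold change -3.30) and BAX fell by 0.83 on the log2 scale, while BAD (0.28) and BID (0.31) rose. In death receptor signalling 5 of 13 genes rose and 7 fell, 5 and 8 adjusted over the list alone (camera adjusted p = 0.668). The decoy receptor gene TNFRSF10D (2.85) and the death receptor gene TNFRSF10B (1.04) rose, and FAS (-2.13) and TNFSF10, which encodes the ligand TRAIL (-3.23), fell.

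**Figure D3:**
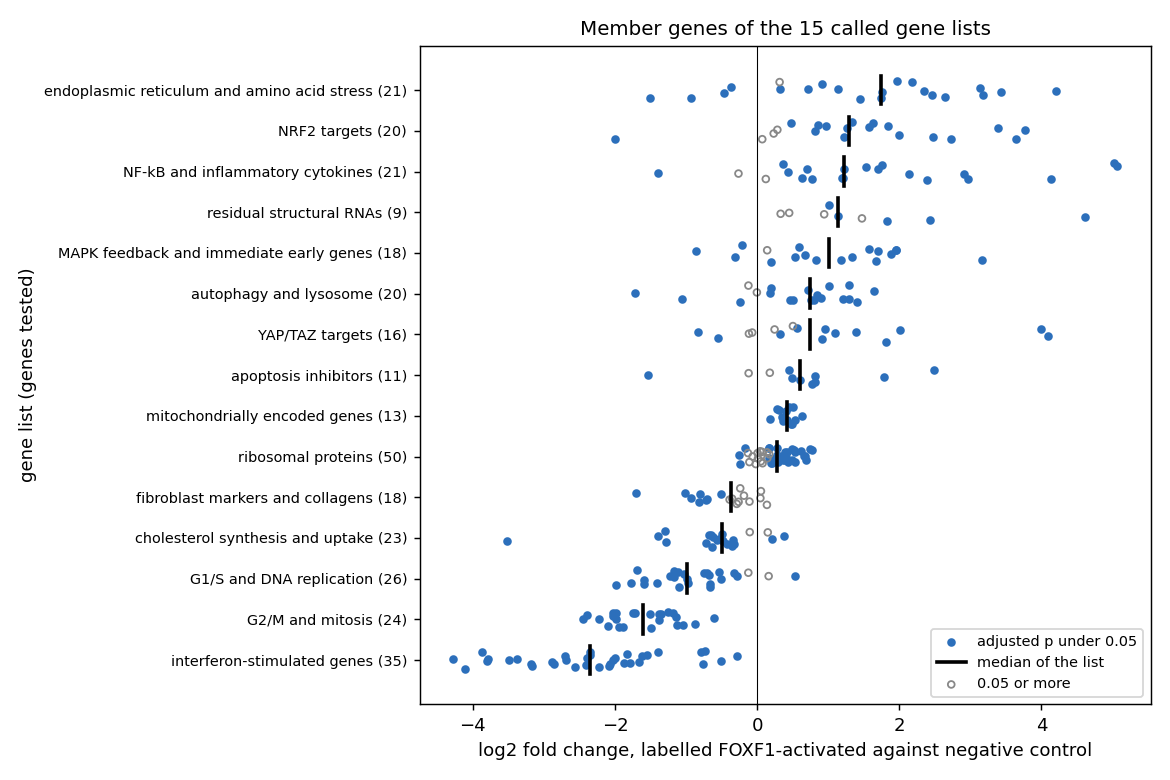
Fitted log2 fold change (x axis) of each member gene in the 15 gene lists called by camera with the preset correlation (y axis, genes tested in brackets), libraries labelled FOXF1-activated against negative control; filled points passed the gene test, open points did not, and black lines are list medians. Medians ran from -2.35 for interferon-stimulated genes to 1.75 for endoplasmic reticulum and amino acid stress; with an estimated correlation 0 lists were called, and under GC and length offsets 2 of the 13 mitochondrially encoded genes were lower.

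Of 18 fibroblast markers and collagens, 8 fell and 0 rose, 8 and 0 adjusted over the list alone (median -0.37, camera adjusted p = 0.0107, and adjusted p = 0.647 with an estimated correlation), and 14 fell without FOXF1-activated replicate 3. COL6A1 fell by 1.71 on the log2 scale and LOXL2 by 1.01. Mesenchymal transition genes were not called as a set (3 of 17 higher and 6 lower, 3 and 6 adjusted over the list alone, camera adjusted p = 0.437), yet FN1 fell from 32495 ± 1162 to 2898 ± 38 CPM, a log2 fold change of -3.49 with a standard error of 0.05 (edgeR adjusted p = 6.39e-10). The matrix gene TNC (-1.97) and the receptor kinase gene AXL (-0.83) fell, and SPARC rose (0.63). Integrins were 4 higher and 8 lower of 16, 4 and 9 adjusted over the list alone (camera adjusted p = 0.366), with ITGA3 at -2.48, ITGB3 at -2.96 and ITGB1 at 0.70. Matrix proteases and invasion genes were 6 higher and 6 lower of 16, 6 and 6 adjusted over the list alone (camera adjusted p = 0.861), with opposite net directions in camera and fry. The protease inhibitor gene TIMP2 (-2.12) and the plasminogen activator gene PLAT (-2.31) fell, and PLAUR (1.40) rose.

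Lineage markers gave no called list beyond the collagens. Epithelial junction and keratin genes were 3 higher and 10 lower of 15, 3 and 11 adjusted over the list alone (camera adjusted p = 0.194), and 6 lower of 11 with the 1 CPM filter, with KRT7 at -1.41, OCLN at 2.05 and CLDN1 at 0.57. CDH1 was below the count filter. Luminal urothelial markers were 4 higher and 5 lower of 12, 4 and 5 adjusted over the list alone (camera adjusted p = 0.861), and their median (-0.10) and mean (0.04) differed in sign. The median turned under upper-quartile scaling (0.0023) and with counts divided by 4 (0.24), and 2 were higher without negative control replicate 2 or 3 or FOXF1-activated replicate 1. Among them TBX2 (1.93) and FOXA1 (1.19) rose and ERBB2 (-0.84) fell. Of the basal and squamous markers 5 were tested, 2 higher and 2 lower, 2 and 3 adjusted over the list alone. Their median (-0.13) and mean (1.60) differed in sign (camera adjusted p = 0.861). EGFR fell by 0.52 on the log2 scale, and KRT17 (5.21) and PI3 (3.65) rose from 4 and 70 control counts. All 4 KRT17 counts lay in negative control replicate 1, so the 8.67 fitted without it stands against 0 control counts and depends on the prior count. Under upper-quartile scaling 1 of these markers was lower, and with the 1 CPM filter or counts divided by 4, which removed KRT17, 1 was higher. Smooth muscle markers were 1 higher and 4 lower of 12, 1 and 4 adjusted over the list alone (camera adjusted p = 0.761), and 2 higher under upper-quartile scaling or the 1 CPM filter, with MYL9 at -2.55 and TAGLN at 1.78. Endothelial markers were 4 higher and 0 lower of 12, 4 and 0 adjusted over the list alone (camera adjusted p = 0.366), with FLT1 at 2.28 and ROBO4 at 1.29. Leukocyte markers were 3 higher and 2 lower of 11, 2 and 2 adjusted over the list alone (camera adjusted p = 0.861), with opposite net directions in camera and fry. CD68 (-2.84) and CD14 (-2.73) fell, and PTPRC (0.38), CD3E (0.65) and CD3D (0.96) rose. With library totals only 1 marker was higher and with no filter 0. Without negative control replicate 2, 0 were higher (0.27, 0.59 and 0.79 for PTPRC, CD3E and CD3D). Without negative control replicate 3 these 3 lost their calls (0.38, 0.47 and 0.69) and FCER1G, with 10 control counts in all, was the 1 marker higher (6.48). PTPRC also lost its call without FOXF1-activated replicate 1 (0.32), CD3E without FOXF1-activated replicate 3 (0.58), and CD3D without FOXF1-activated replicate 1 (0.77), 2 (1.07) or 3 (1.02) and under GC and length offsets (0.73).

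Among developmental pathways, hedgehog genes, through which FOXF1 is regulated in development, were 2 higher and 4 lower of 11, 2 and 4 adjusted over the list alone (camera adjusted p = 0.805). GLI3 (-1.27), GLI2 (-1.72) and SUFU (-0.42) fell and GLI1 (1.12) rose. TGF-beta targets were 4 higher and 5 lower of 15, 4 and 5 adjusted over the list alone (camera adjusted p = 0.861), with a median of 0.08 (-0.005 without negative control replicate 1, -0.063 without FOXF1-activated replicate 1) and a mean of -0.22. PMEPA1 (-2.22) fell and TGFB2 (1.81) rose. Wnt/beta-catenin targets were 2 higher and 5 lower of 13, 2 and 5 adjusted over the list alone (camera adjusted p = 0.861), with opposite net directions in camera and fry. MYC rose by 1.25 and LGR5 fell by 4.10 on the log2 scale.

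All 13 mitochondrially encoded protein genes rose, 13 adjusted over the list alone, by a median of 0.43 (camera adjusted p = 1.08e-04, and adjusted p = 0.630 with an estimated correlation), but with offsets for GC content and length 4 were higher, 2 were lower and 7 did not pass. MT-ND2 rose from 2384 ± 142 to 3702 ± 287 CPM (log2 fold change 0.64). Ribosomal protein genes were higher for 34 of 50 and lower for 3, 35 and 3 adjusted over the list alone (median 0.28, camera adjusted p = 2.00e-05, and adjusted p = 0.769 with an estimated correlation), with RPL30 at 0.68 and RPL4 at 0.53, genes whose processed pseudogenes can share reads. The lower ones were 5 with library totals only and 1 under upper-quartile scaling or GC and length offsets. Among 9 residual structural RNAs tested as a sign of RNA quality and depletion, 5 were higher and 0 lower, 5 and 0 adjusted over the list alone (median 1.14, camera adjusted p = 0.0298, and adjusted p = 0.416 with an estimated correlation). MT-RNR2, the large mitochondrial ribosomal RNA, rose by 1.14 and SNORD3A by 4.61. Nuclear-retained long noncoding RNAs were 3 higher and 5 lower of 11, 3 and 5 adjusted over the list alone (camera adjusted p = 0.735), with NEAT1 at -2.24, MALAT1 at -0.84 and PVT1 at 1.33.

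The tests used edgeR's quasi-likelihood fit with Benjamini-Hochberg adjustment for genes and camera for lists. No label gives a culture, preparation or sequencing batch, so a batch shared by the 3 libraries of a group and the hairpin cannot be told apart.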

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

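The tests with counts divided by 4, with GC and length offsets and without the 50 most abundant genes were chosen after the results were seen. FOXF1 stayed lower and past the threshold under all 18 alternative settings, with a log2 fold change between -0.60 and -0.41. Among them, the prior count of 2 alters only the fitted fold change and leaves the test unchanged, so it could not lose the call. The count of changed genes ranged from 11014 of 14638 tested with the 1 CPM filter to 12831 of 20334 with limma-voom, within 1.5 times of 12351. With no filter 11729 of 34175 genes were called, so the share of tested genes moved more than the count. A fit with the replicate block called 11790 genes and 15 lists. Libraries with the same number did not deviate together (correlations of -0.02, -0.001 and -0.02), and no library correlated best with that of its own number, so the numbers were not read as pairs. Gene lists called moved from 15 to 0 with an estimated correlation and to 30 by fry, which tests another question. The sign turned for FOXC2 under upper-quartile scaling (0.025) and under GC and length offsets (0.21), and for MT-ATP8 (-0.13) and MT-ND3 (-0.058) under those offsets. Leaving out a library gave -0.49 to 0.046 for FENDRR and -0.15 to 0.015 for FOXC2. None of these named values passed the threshold in edgeR once reversed, but under GC and length offsets 6 of all changed genes were called in the opposite direction, and 2 of 13 mitochondrially encoded genes were called lower. The direction of uncalled lists turned under fry for caspases (adjusted p = 0.834), leukocyte markers (0.275), Wnt/beta-catenin targets (0.258) and matrix proteases (0.0453), and for leukocyte markers with the 1 CPM filter (0.934). Depth, possibly overstated, limits genes with few control counts.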

Other observations

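The tests on the 8 gene lists of the next paragraph, on mislabelled single libraries, scaling, exchange of whole groups, leukocytes, a preparation batch, GC and length offsets and the most abundant genes were chosen after related results had been seen.

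Antigen presentation and protein turnover genes also differed, in lists drawn up after the interferon and stress results and adjusted over these 8 lists. All 15 genes of MHC class I antigen presentation were lower in the libraries labelled FOXF1-activated, with a median log2 fold change of -1.10 (camera adjusted p = 6.48e-08, and adjusted p = 0.0304 with an estimated correlation). The genes named in this paragraph were chosen after their values were seen. HLA-B fell from 85.0 to 36.5 CPM, TAP1 from 62.3 to 32.5 CPM and the immunoproteasome gene PSMB9 from 17.3 to 3.32 CPM. Constitutive proteasome subunits were higher for 24 of 31 and lower for 2 (median 0.63, camera adjusted p = 3.97e-08, and adjusted p = 0.179 with an estimated correlation), with PSMD2 rising from 682 to 1694 CPM and 1 subunit lower under upper-quartile scaling. Genes of endoplasmic reticulum translocation and glycosylation rose for 14 of 16 (median 0.72, camera adjusted p = 1.11e-07, and adjusted p = 0.155 with an estimated correlation), though 1 was lower under GC and length offsets. Those of endoplasmic reticulum associated degradation rose for 9 of 12 and fell for 2 (median 0.95, camera adjusted p = 0.00121, and adjusted p = 0.0902 with an estimated correlation), with SEL1L rising from 133 to 418 CPM. All 5 tested metallothioneins fell (median -2.43, camera adjusted p = 0.00121, and adjusted p = 0.155 with an estimated correlation), MT2A from 528 to 163 CPM; reads of these paralogs and of the HLA genes can be shared between copies. Aminoacyl-tRNA synthetases (13 of 20 higher, 4 lower, camera adjusted p = 0.0117), heat shock proteins (10 of 14 higher, 3 lower, 0.0346) and the nuclear-encoded respiratory chain (13 of 25 higher, 5 lower, 0.0349) were called higher, each with an adjusted p of 0.416 with an estimated correlation.

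FOXF1 was lower in the libraries labelled FOXF1-activated. A mislabelled library or an exchanged pair is argued against, since 0 libraries lay in the other group's FOXF1 range or on its side of the first principal component. The choice of scaling is argued against by the highest FOXF1 log2 fold change over 5 scalings, -0.41. All of these scalings rest on the gene counts themselves, so a difference in total RNA between the groups was not tested. Reads shared with an overlapping gene of GENCODE 29 are argued against by 0 bases of other genes' exons inside the FOXF1 exons. In that release FENDRR, the nearest neighbour, ends 1427 bases away. Overlap with counted genes that GENCODE 29 lacks, and reads that map to several places, were not tested. An exchange of the labels of whole groups would give the same size of difference, 0.51, and cannot be told apart from correct labels, because no other gene's direction under the activating hairpin was set in advance. A fall of FOXF1 with the hairpin stays open as a hypothesis and was not tested.

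Interferon-stimulated genes were lower in the libraries labelled FOXF1-activated, by a median of -2.35. A general fall at their expression level is argued against by the lowest median of 10000 random matched lists, -0.83, and GC content and length by the median of -2.20 left after their trend was removed. A general excess of leukocytes in the control libraries is argued against by PTPRC, which was not lower (log2 fold change 0.38, edgeR adjusted p = 0.0243, a call lost with library totals only at 0.30, with no filter at 0.35, without negative control replicate 2 at 0.27, without negative control replicate 3 at 0.38 and without FOXF1-activated replicate 1 at 0.32), and by LYZ at 56 counts over the controls, although CD14 (-2.73) and CD68 (-2.84) fell. PTPRC held 2685 counts over the controls and 3250 over the other group. Its transcript was thus present in both groups, and the cells it came from were not tested. Less interferon transcript may contribute, but 0 interferon genes were called lower by edgeR among the tested ones, where IFNE alone passed the filter with 77 and 80 counts (log2 fold change 0.12, adjusted p = 0.910) and below it IFNB1 held 12 control counts and 0 in the other group, IFNG 4 and 0, IFNW1 8 and 4 and IFNK 0 and 8, so this stays open. A difference in the response to the hairpins, which the labels would allow, was not tested.

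Of the tested genes 60.7% changed. Among the 10 splits of the 6 libraries only the real one (1 of 10) gave 12351 genes, the highest other split giving 0 by edgeR (at most 134 at an unadjusted p under 0.05) and 0 by limma-voom, but 10 splits are too few for a share under 0.05. Every other split mixes the labels, so the label difference enters its spread within groups. Few calls were therefore bound to come from these splits, and they do not show how many genes would be called without a difference. Abundant genes are argued against by 12304 genes called without the top 50, and GC content and length by 12214 called with offsets. A cell line or subclone with other copies of whole autosomes is argued against by a largest autosome deviation of 0.14 in median log2 fold change. Changes of part of a chromosome, or a subclone with the same copies, need not move these medians and stay open. A preparation batch shared by a group may contribute, as residual structural RNAs differed by a median of 1.14, and cannot be told apart from the hairpin because no label gives a batch.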
